A study of Schizosaccharomyces pombe with 7 samples.

How the data were processed

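The data were 7 microarrays of H3-FLAG chromatin immunoprecipitation (ChIP-chip) in 4 genotypes of Schizosaccharomyces pombe: 3 of wild type, 2 of fft3Δ, and 1 each of clr3Δ and fft3Δ clr3Δ. Cells grew in minimal medium at 30 °C, and expression of tagged H3 was induced in cells blocked in S phase with hydroxyurea. DNA was sheared to fragments of 500 to 1000 bp and amplified by random-primed PCR, per the labels' protocols. Red (Cy5) was ChIP DNA and green (Cy3) whole-cell extract DNA (input) on every array, with no dye swap, so a dye bias of single probes cannot be told from enrichment in a level but cancels in a difference between genotypes. Fragments of this length blur the edges of any region over several probes.

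The deposited scanner values are intensities from Agilent Feature Extraction, a tool named in the submitters' processing notes; the file headers give version 10.7.3.1 for slide 1 and 12.0.3.1 for slides 2 and 3. Processed intensities had the background subtracted and a linear dye normalization applied, per the file headers, which makes the mean level of an array uninformative about the total amount of new H3. The median intensities of spot and local background were deposited uncorrected. The deposited series table holds log2 values, found here to equal the log2 ratio of red to green processed signals of the same array to within 4.9e-08, neither centred nor scaled; its column medians were −0.037, −0.042, 0.018, 0.0017, −0.0014, −0.029 and −0.043 (wild type 1, fft3Δ 1, wild type 2, fft3Δ 2, wild type 3, clr3Δ, double mutant). The log10 column of the deposited scanner values is the log10 ratio of red to green processed signals, checked against them. Other deposited columns used were flags of 0 or 1 for spots that were nonuniform, population outliers, saturated or well above background, per the file headers. The genome build of the probe names is not given in the sources used here.

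Probes were placed on the reference ASM294v3 from the file coordinates, by the offset at which the mean log2 input signal followed the GC content of the reference best (correlation with a quadratic fit). Blocks of 10 kb along chromosome II showed a step inside centromere 2: file coordinates exceeded the reference by 900 bases left of it, by 1800 bases right of it and at the right end of the chromosome, and by 0 at the left end of chromosome III. The correlation at the chosen offset was 0.646, 0.636 and 0.681 for the chromosome II stretches, against at most 0.247, 0.249 and 0.278 at other offsets, but 0.452 against 0.351 for chromosome III, whose placing is therefore weak. Of 43993 probes 42972 were placed, 824 belong to a mating-type contig kept in its own coordinates, and 197 in 3 short segments were left unplaced; the right part of the contig was tried from 3 starts and is not used in any comparison. A probe was called repeated if the central bases of its placed sequence occur more than once in the reference on either strand: 94.2% of the 590 probes of the outer repeats, 81.2% of the 999 of the subtelomere, 30.3% of the 198 of the central core, 27.5% of the 480 of the mating-type region and 98.1% of the 160 in Tf2. Centromeres 1 and 3, the subtelomere-adjacent stretches, tlh1, inv1, fft3 and clr3 are not analysed here.

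For each probe the log2 ratio of red to green processed signal was centred on the median of its array, without the spots marked as nonuniform or population outliers (4 to 929 per array). Values of genes with at least 2 probes were averaged over probes; 1953 of the 2220 genes share a probe with another gene, so neighbouring calls are not independent. Gene values were fitted with limma 3.58.1 in R 4.3.3 with a mean per genotype over all 7 arrays, and called at a Benjamini-Hochberg adjusted p under 0.05. The single arrays of clr3Δ and the double mutant add nothing to the estimate of spread and are assumed to vary like wild type and fft3Δ. Regions were averaged over their probes, with an exact two-sided permutation for fft3Δ against wild type. They were also tested with camera over windows of 2 kb at a preset correlation of 0.01, on which calls rest unless stated. The estimated correlations were higher: 0.62 at the outer repeats, 0.95 at the core, 0.65 at the mating-type region, 0.067 at the subtelomere and 0.70 at Tf2. The p-values at the preset correlation therefore overstate the evidence. Gene lists were tested with camera on gene values. The smallest list (5 genes) and region (2 windows) so tested were set after the data were seen. The interaction is the double mutant minus clr3Δ, minus the difference of fft3Δ and wild type. Input was compared with limma in 5-kb windows of the centred log2 green signal. Slide held more than 1 genotype throughout, so values are given with slide as a block and within each slide. The block leaves fewer residual degrees of freedom than the 3 of the main fit. Its camera p-values are at the preset correlation only. The arrays of wild type and fft3Δ on a slide deviated together (correlation over genes 0.564 on slide 1 and 0.322 on slide 2).

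Groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for fft3Δ, the 10 highest and 10 lowest genes past the test with the same sign on both slides, filled up by the moderated t where fewer passed. For clr3Δ and the double mutant it took 6 and 6. It also took the 2 largest differences of each gene list, preferring those past the test, and always fft3, clr3, inv1, tlh1, tlh2, mei4 and act1. The 21 lists held ribosomal protein, translation factor, glycolysis, histone, chaperone, core stress, phosphate, sugar, G1/S and replication, iron, meiotic, subtelomeric marker, heterochromatin factor, mating, cell wall, amino acid permease, Tf2, tRNA, snoRNA and snRNA, rRNA and long noncoding RNA genes; 0 members of the translation factor and phosphate lists were measured. The rRNA list was fixed as one of 5S rRNA genes, but its name pattern took in all 14 measured rRNA genes: 7 annotated as 5S on chromosome II and 7 of other kinds in the ribosomal DNA at the left end of chromosome III (III: 1–23130). List members were first matched through older symbols as well, which had taken in 4 wrong genes. Matching was limited to current symbols and identifiers after values had been seen, and this ended a call of the core stress list between the double mutant and clr3Δ.

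Alternatives were normexp background correction with an offset of 50 (on median signals, since mean signals were not used here), scaling to equal spread, centring on arm probes, quantile normalization, loess within arrays, the deposited log2 table, probes well above background alone, probes found once alone, the median over probes, at least 4 probes per gene, slide as a fixed or random block, single slides, wild type and fft3Δ alone, an intensity trend with robust variance, a threshold of 0.01, each replicate left out, an estimated correlation, and windows of 1 and 5 kb. Leaving out both arrays of slide 1, and limiting the mating-type region to the interval from rpp202 to emc3, were added after seeing the data, as were correlations between differences that share no control and the split of the rRNA list by these places. On simulated data with 200 of 2220 genes changed, the fit for fft3Δ recovered 77.9% of genes changed by a log2 difference of 0.5 and 100% at 1, with 5.19% of its calls wrong. For clr3Δ these were 46.3%, 98.5% and 5.81%, and for the double mutant 38.5%, 99.7% and 5.58%. Of 20 simulated sets of 25 genes shifted by 0.3 camera found 20, and of unshifted sets 0. Simulated genes were drawn independently and without a slide effect, so these rates need not hold for the arrays. Genes of fft3Δ with differences near 1 did not pass.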

Results

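Newly made histone H3 was followed in fission yeast (Schizosaccharomyces pombe) cells held in S phase with 15 mM hydroxyurea (HU), a drug that stops DNA replication. After 4 h of HU the medium was changed from 8% glucose to 4% sucrose for 2 h, still with HU, which switched on a FLAG-tagged H3 that marks nucleosomes assembled in that time. Chromatin was fixed with 1% formaldehyde, and DNA bound to tagged H3 was recovered with an anti-FLAG antibody (ChIP) and hybridised in red (Cy5) beside whole-cell extract DNA (input) in green (Cy3). The 4 genotypes were wild type with 3 arrays, fft3Δ with 2, and clr3Δ and the double mutant fft3Δ clr3Δ with 1 each. Fft3 is a chromatin remodeller of the Snf2 family, and Clr3 is the histone deacetylase of the SHREC complex that silences heterochromatin. The title of the series names suppression of nucleosome turnover by Fft3 as its subject.

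The arrays carried 43993 probes of 60 bases, 1 every 50 bases, over a 2.05 Mb block of chromosome II that holds centromere 2, the right subtelomere of chromosome II, the left end of chromosome III, and a separate mating-type contig. They measured 2220 genes with a median of 21 probes: 894 protein-coding, 1261 long noncoding RNA, 25 tRNA and 40 others. The medians of the processed input signal lay between 1129 and 1363, and those of the ChIP signal between 1126 and 1358. At least 99.44% of the probes were well above background on every array in each channel, and 0 spots were saturated. Slide 1 held wild type and fft3Δ (replicate 1 of each), slide 2 their second replicates, and slide 3 the third wild-type array, clr3Δ and fft3Δ clr3Δ. Across probes, which are not independent replicates, wild type and fft3Δ correlated at 0.908 on slide 1 and 0.870 on slide 2. The third wild-type array correlated with clr3Δ at 0.757 and with the double mutant at 0.521. The genes fft3 and clr3 lay outside the stretches analysed here, so the deletions themselves were not checked, and the labels do not say that arrays of a genotype came from separate cultures. The limma and permutation p-values then measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision of every value. Those of camera at the preset correlation set windows or genes against all others, nearly as if independent. They do not stand for replicate arrays.

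In wild-type cells new H3 was scarcest over the central core of centromere 2 (II: 1619261–1629170, ASM294v3), where the H3 variant Cnp1 replaces H3 in many nucleosomes. The mean log2 ratio of ChIP to input there, with each array centred on its median, was −3.03 ± 0.32 (SD, n = 3). The outer centromere repeats on both sides (1602411–1643870), which are packed into heterochromatin, stood at −1.40 ± 0.08 and the right subtelomere of chromosome II (4489801–4539760) at −0.64 ± 0.10. On each of the 3 wild-type arrays the core lay below the outer repeats and these below the subtelomere. The silent mating-type region (2114011–2138020) was near the array median at −0.04 ± 0.16, as was the chromosome arm at 0.06 ± 0.01. That region was not uniform: its right part, the interval from rpp202 to emc3 (2128461–2138320), chosen after seeing the data, stood at −0.67 ± 0.34. Wild-type arrays also differed from each other in input at stretches of the mating-type contig, so differences at this region may compare unlike loci. The pair of Tf2 retrotransposons, Tf2-9 and Tf2-10, averaged 0.53 ± 0.10. Among named genes, hht2, which encodes histone H3, stood at 1.47 ± 0.15, the small heat shock gene hsp16 at 1.44 ± 0.04, and the subtelomeric helicase gene tlh2 at −1.04 ± 0.17. These levels were described and not tested against each other.

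**Figure D1:**
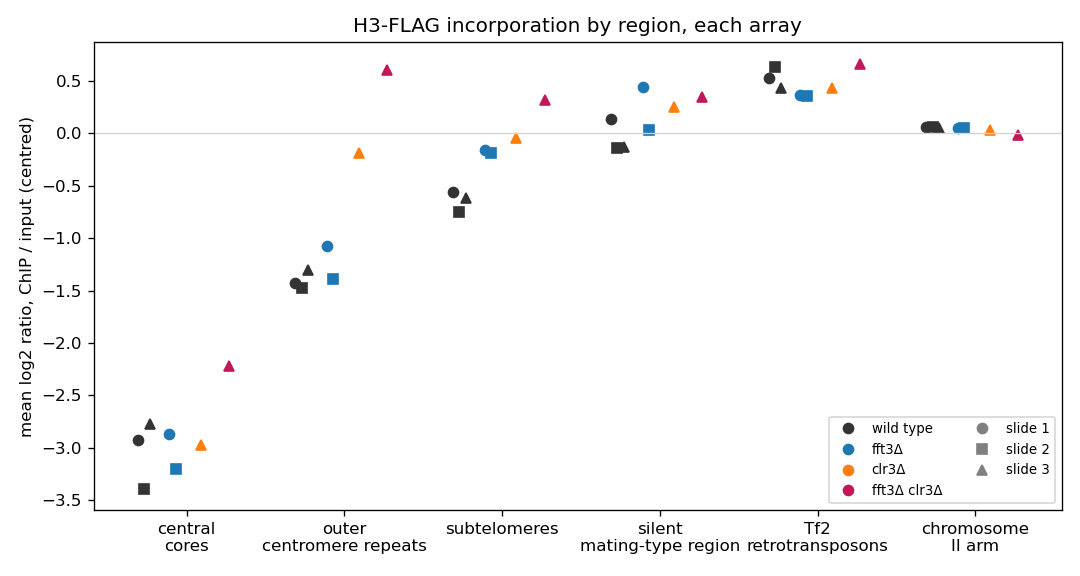
Mean centred log2 ratio of H3-FLAG ChIP to input (vertical axis) for each array in 6 regions (horizontal axis), coloured by genotype with the marker giving the slide. The wild-type arrays lie between −3.39 and −2.77 in the central core, and at the outer repeats the double mutant (0.60) and clr3Δ (−0.19) lie above every wild-type and fft3Δ array.

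Loss of Fft3 raised the incorporation of new H3 over the right subtelomere of chromosome II. The mean log2 ratio there was −0.18 ± 0.02 in fft3Δ (SD, n = 2) against −0.64 ± 0.10 in wild type (n = 3), a difference of 0.46 ± 0.07 (SE). All 5 stretches of 10 kb from the chromosome end inward were higher, by 0.32, 0.42, 0.63, 0.56 and 0.37. The difference was 0.39 within slide 1, 0.55 within slide 2 and 0.47 with slide as a block. It was 0.38 at the 188 probes whose central bases occur once in the reference, with near copies not counted. The set test camera over 26 windows of 2 kb gave an adjusted p = 4.48e-37 at a preset correlation of 0.01, and adjusted p = 0.0136 with an estimated correlation. The exact two-sided permutation of the 5 arrays gave p = 0.1, the smallest that its 10 splits allow, so that test could not pass the threshold.

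No single gene passed the test between fft3Δ and wild type. The 10 genes ranked highest all belonged to the right subtelomere, and their values are given although they did not pass. SPBCPT2R1.02 (4508450–4508809) differed by 1.09 ± 0.17 (SE, limma adjusted p = 0.165), with 0.94 on slide 1 and 1.22 on slide 2. The noncoding RNA genes SPNCRNA.6638 beside it and SPNCRNA.6639 differed by 1.04 and 0.85, each with a limma adjusted p = 0.165. SPBCPT2R1.03, the pseudogene SPBCPT2R1.06C, SPNCRNA.6643, SPBCPT2R1.04c, SPBCPT2R1.01c and SPNCRNA.6635 differed by 0.81, 0.72, 0.64, 0.55, 0.54 and 0.44. The galactokinase gene gal1 (4488298–4490271), with 9 probes, none of them repeated, differed by 0.63 ± 0.14 (limma adjusted p = 0.512, with 0.73 and 0.55 on slides 1 and 2). Probes of this end of the chromosome begin at 4489801, so they cover only part of gal1. The inner limit of the rise was therefore not measured. For tlh2 (4526885–4532899) the difference was 0.39 ± 0.12 (limma adjusted p = 0.999). The 10 ranked lowest all lay on the arm and differed by −0.27 to −0.22, each with a limma adjusted p = 0.999: SPNCRNA.5205, SPNCRNA.5344, SPNCRNA.5151, SPNCRNA.5082, SPNCRNA.5186, SPNCRNA.5353, gcn20, irs1, vhc1 and vps38. limma called 0 of 2220 genes higher and 0 lower, against 63 and 8 at an unadjusted p under 0.05. With an intensity trend and robust variance 5 genes were called higher (SPBCPT2R1.02, SPBCPT2R1.03, SPNCRNA.6638, SPNCRNA.6639 and gal1), and with slide as a random block 3 (SPBCPT2R1.02, SPNCRNA.6638 and SPNCRNA.6639). Without wild-type replicate 1 there were 7, among them SPBCPT2R1.02, SPBCPT2R1.03, SPNCRNA.6638 and SPNCRNA.6639 (adjusted p = 0.0457 each).

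A further 3 regions passed camera at the preset correlation and not with an estimated one. The outer repeats of centromere 2 were higher in fft3Δ by 0.17 ± 0.13 (SE), the silent mating-type region by 0.28 ± 0.20, and the Tf2 elements were lower at −0.17 ± 0.08. The camera adjusted p-values were 4.54e-06, 1.23e-06 and 0.00163, and adjusted p = 0.254 with an estimated correlation for each. Exact permutation gave p = 0.3, 0.3 and 0.2. Within slides 1 and 2 the outer repeats differed by 0.35 and 0.083, the mating-type region by 0.30 and 0.18, and Tf2 by −0.17 and −0.28; with slide as a block the values were 0.22, 0.24 and −0.22. Without replicate 1 of fft3Δ the calls at the outer repeats (0.014) and the mating-type region (0.075) ended, and without its replicate 2 these values were 0.33 and 0.49. Quantile normalization turned the outer repeats to −0.017, and loess within arrays turned Tf2 to 0.045. The central core did not differ past the test (−0.0032 ± 0.27, exact permutation p = 1, camera adjusted p = 0.965; 0.062 and 0.19 within the slides, 0.13 with the block). It passed as lower without wild-type replicate 2 (−0.18) and with normexp background correction (−0.35), and as higher with arrays scaled to equal spread (0.35). The arm differed by −0.011 and the solitary long terminal repeats (LTRs) on it by −0.037 ± 0.06, exact permutation p = 0.6.

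Of the gene lists tested as sets, the 25 tRNA genes rose in fft3Δ, by 0.12 on average, with camera adjusted p = 0.00591; adjusted p = 0.763 with an estimated correlation. Their mean difference was 0.044 on slide 1 and 0.31 on slide 2, and 0 of the 25 passed singly. Camera with slide as a block gave an adjusted p = 5.2e-06. That p is at the preset correlation too, and the slides disagree in size, so it is no stronger evidence. SPBTRNAARG.06 and SPBTRNAARG.07 differed by 0.32 and 0.24. The list's call ended with loess within arrays (adjusted p = 0.0821), and 0 lists passed without replicate 1 of fft3Δ and 3 without its replicate 2. The other lists tested did not pass: 25 ribosomal protein genes (mean 0.065, adjusted p = 0.171), 14 snoRNA and snRNA genes (0.072, 0.171), 1266 long noncoding RNA genes, 5 of them annotated only as noncoding (0.025, 0.246), 5 mating genes (0.12, 0.347), 14 rRNA genes (−0.031, 0.575) and 5 core stress response genes (0.013, 0.86). With quantile normalization the ribosomal protein genes passed as higher (0.063) and the rRNA genes as lower (−0.10), each with an adjusted p = 0.0403, and with loess the rRNA genes turned to 0.080. With slide as a block their adjusted p-values were 0.979, 0.104, 0.104, 0.979, 0.381 and 0.979. Slides 1 and 2 gave means of 0.12 and −0.12 for ribosomal protein genes, 0.13 and 0.055 for snoRNA and snRNA genes, 0.032 and 0.028 for long noncoding RNA genes, and 0.27 and −0.18 for mating genes. For rRNA genes they gave 0.035 and −0.13, and for core stress genes 0.017 and 0.0053. The rRNA list joins 7 genes annotated as 5S on the arm of chromosome II and 7 genes of the ribosomal DNA at the left end of chromosome III, whose probes are all repeated. Taken apart, a choice made after seeing the data, they averaged 0.024 (adjusted p = 0.786; 0.099 and −0.072 on slides 1 and 2) and −0.087 (0.258; −0.029 and −0.18). The arm genes turned to −0.055 with equal spread, −0.033 with quantile normalization and −0.11 without replicate 1 of fft3Δ, and passed as higher with loess (0.23) and without its replicate 2 (0.16). Those of the ribosomal DNA turned to 0.040 with equal spread and passed as lower with normexp (−0.26) and quantile normalization (−0.17). No member of any list passed over all genes. Adjusted over the list alone, tlh2 passed and no member of another list did. As tlh2 is the single measured subtelomeric marker, its p-value there was in effect unadjusted.

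In fft3Δ the largest differences within the lists too short for a set test belonged to genes that did not pass. Values were −0.27 ± 0.21 (SE) for the enolase gene eno101 and −0.17 ± 0.23 for tdh1 (glycolysis, 4 genes), 0.14 ± 0.17 for the H2A variant gene pht1 and 0.085 ± 0.11 for hhf2 (histones, 3), and −0.089 ± 0.11 for hsp16 and −0.068 ± 0.15 for mas5 (chaperones, 3). The G1/S and replication genes (3) gave −0.028 for mcm2 and 0.024 for yox1, the iron genes (2) 0.15 for str1 and −0.0033 for php4, and the meiotic genes (4) 0.15 for rep1 and 0.059 for rec8. The heterochromatin factor genes (2) gave −0.075 for clr1 and −0.048 for tas3, and the cell wall genes (2) −0.096 for bgs1 and −0.0016 for gas2. The amino acid permease gene fnx1 differed by −0.18, the glucose repressor gene scr1 by 0.039, Tf2-10 by −0.18 and Tf2-9 by −0.17. The actin gene act1 differed by 0.18 ± 0.16 and mei4 by 0.025 ± 0.11. Members of the tested lists with the largest differences were rpp202 (0.38) and rpl2502 (0.22), snoU14 (0.32) and snR92 (0.28), mat3-Mi (0.25) and mat1-Mi (0.18), SPRRNA.50 (−0.19) and SPRRNA.44 (−0.13), and gpx1 (0.20) and atf21 (−0.17).

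Loss of the deacetylase Clr3 raised new H3 at the outer repeats of centromere 2, the largest rise among the 5 regions tested, where the log2 ratio was −0.19 on the single clr3Δ array against −1.40 ± 0.08 in wild type (n = 3). The difference was 1.21 ± 0.17 (SE, with the spread taken from the replicated genotypes) and 1.12 against the wild-type array of its own slide. The left and right repeats differed by 1.22 and 1.20, which are not independent values, since 94.2% of the probes are repeated sequences. The right subtelomere rose by 0.59 ± 0.09 (0.57 on slide 3), most between 10 and 20 kb from the end (0.91). The camera adjusted p was 3.36e-46 for the outer repeats (adjusted p = 0.0345 with an estimated correlation) and 9.03e-30 for the subtelomere (adjusted p = 0.0197 with an estimated correlation). The mating-type region rose by 0.29 ± 0.25 (0.38 on slide 3; camera adjusted p = 0.00463, and adjusted p = 0.578 with an estimated correlation), and this call ended at probes found once in the genome (0.08). The central core (0.06 ± 0.34, −0.20 on slide 3, camera adjusted p = 0.566) and Tf2 (−0.10 ± 0.10, −2.44e-05 on slide 3, camera adjusted p = 0.499) did not pass. Slide 3 alone carried clr3Δ, so the value with slide as a block was that of slide 3.

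In clr3Δ limma called 31 genes higher and 0 lower of 2220, against 90 and 13 at an unadjusted p under 0.05. Of the 31, 25 were among the 35 genes of the outer repeats and 6 among the 48 of the right subtelomere, and all 31 had the same sign within slide 3. The largest was SPNCRNA.5270 (1634960–1635318), a noncoding RNA gene of the right outer repeats, at 1.56 ± 0.16 (SE, limma adjusted p = 0.00392; 1.51 on slide 3). SPNCRNA.5271, SPNCRNA.5259, SPNCRNA.5274, SPNCRNA.362 and SPNCRNA.5275 rose by 1.47, 1.39, 1.38, 1.38 and 1.36; the call of SPNCRNA.5259 ended with loess within arrays (1.31, adjusted p = 0.106). In the subtelomere tlh2 rose by 1.00 ± 0.16 (limma adjusted p = 0.0171; 1.14 on slide 3), a call that ended with arrays scaled to equal spread (1.03, adjusted p = 0.055). The other subtelomeric calls, named after their values were seen, were SPNCRNA.6643, SPNCRNA.6645, SPNCRNA.6647, SPNCRNA.6651 and SPNCRNA.6652. The genes ranked lowest did not pass: SPNCRNA.5029 at −0.46 (limma adjusted p = 0.398), then SPNCRNA.5499, SPNCRNA.5435, SPNCRNA.5288, SPBC1709.16c and SPBC409.18 between −0.42 and −0.37. Most of the called genes lie in repeats: with probes found once in the genome 2 genes were called higher. Without wild-type replicate 2 there were 54 higher and 1 lower, and with slide as a random block 50 higher.

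Among the lists, the 25 tRNA genes rose in clr3Δ by 0.15 on average (camera adjusted p = 0.00605; adjusted p = 0.718 with an estimated correlation). That rise was 0.032 on slide 3, did not pass with slide as a block (adjusted p = 0.661), and turned to −0.067 with quantile normalization. SPBTRNAARG.05 and SPBTRNALEU.06 differed by 0.46 and 0.40. The 5 mating genes (mean 0.29, adjusted p = 0.0704) and the 25 ribosomal protein genes (0.037, 0.439) did not pass, but both passed as higher with slide as a block (each adjusted p = 0.00238), with means of 0.45 and 0.16 on slide 3. Long noncoding RNA genes (0.039, adjusted p = 0.104; 0.029 on slide 3, 0.584 with the block), rRNA genes (0.18, 0.119; 0.21, 0.0559), snoRNA and snRNA genes (0.03, 0.439; −0.011, 0.831) and core stress genes (0.045, 0.589; 0.049, 0.661) did not pass. The mating genes passed with equal spread (adjusted p = 0.0437) and, like the rRNA genes, with loess (each adjusted p = 0.0384). Taken apart after seeing the data, the 7 rRNA genes of the ribosomal DNA on chromosome III were higher by 0.45 (camera adjusted p = 0.000352; adjusted p = 0.274 with an estimated correlation; 0.49 on slide 3, 8.5e-05 with the block), and the 7 5S genes of the arm did not pass (−0.098, adjusted p = 0.248; −0.077 on slide 3, 0.534 with the block). The call at the ribosomal DNA ended with quantile normalization (0.21, adjusted p = 0.16). Where 1 list passed here, 3 did without wild-type replicate 1 or 2, and 2 without either replicate of fft3Δ. The median of the long noncoding RNA genes was −0.014, below 0 where their mean was above. Over all genes 30 long noncoding RNA genes and tlh2 passed; adjusted over the list alone they were 38 and tlh2, with 0 members of any other list. Members with the largest differences were rpp202 (0.64, limma adjusted p = 0.413) and rpl802 (−0.22), mat3-Mi (0.52) and mat1-Mi (0.46), SPRRNA.51 (0.54) and SPRRNA.47 (0.53), snoZ30 (−0.20) and SPNCRNA.1483 (−0.17), and atf1 (0.14) and atf21 (0.095). Shorter lists gave −0.45 for eno101 and −0.12 for tdh1, 0.14 for hhf2 and 0.13 for hht2, −0.20 for mas5 and 0.11 for sks2, −0.27 for fnx1 and 0.16 for scr1. They also gave 0.13 for yox1 and 0.12 for cdc18, −0.14 for both php4 and str1, 0.13 for rec8 and −0.11 for spo5, −0.045 for tas3 and −0.042 for clr1, and 0.055 for bgs1 and −0.035 for gas2. Tf2-9, Tf2-10, act1 and mei4 differed by −0.12, −0.089, 0.069 and −0.07.

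In the double mutant new H3 rose further at the outer repeats, to a log2 ratio of 0.60 on its single array, 2.00 ± 0.17 (SE) above wild type (1.91 within slide 3). The subtelomere rose by 0.95 ± 0.09 (0.93 on slide 3), most between 10 and 20 kb from the end (1.32). The central core, which did not pass in either single mutant, rose by 0.81 ± 0.34 (0.55 on slide 3). Protein-coding arm genes on this array followed the wild-type level with a slope of 0.621. Such compression by itself would raise the core, the lowest region in wild type, and was not tested there. The mating-type region rose by 0.39 ± 0.25 (0.48 on slide 3, and 0.20 at probes found once in the genome). The Tf2 elements did not pass (0.13 ± 0.10, 0.24 on slide 3, camera adjusted p = 0.137), but passed as higher without wild-type replicate 2 (0.18), with equal spread (0.22) and with quantile normalization (0.29). The camera adjusted p-values were 2.16e-39 for the outer repeats, 1.39e-29 for the subtelomere, 4.92e-05 for the core and 0.00121 for the mating-type region. In that order they were adjusted p = 0.0441, 0.0199, 0.241 and 0.383 with an estimated correlation. The call at the core ended with quantile normalization (0.026) and with normexp, which turned it to −0.15. Input DNA of the double mutant at the outer repeats was lower than that of the wild-type array on its slide by a log2 difference of −0.51.

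**Figure D2:**
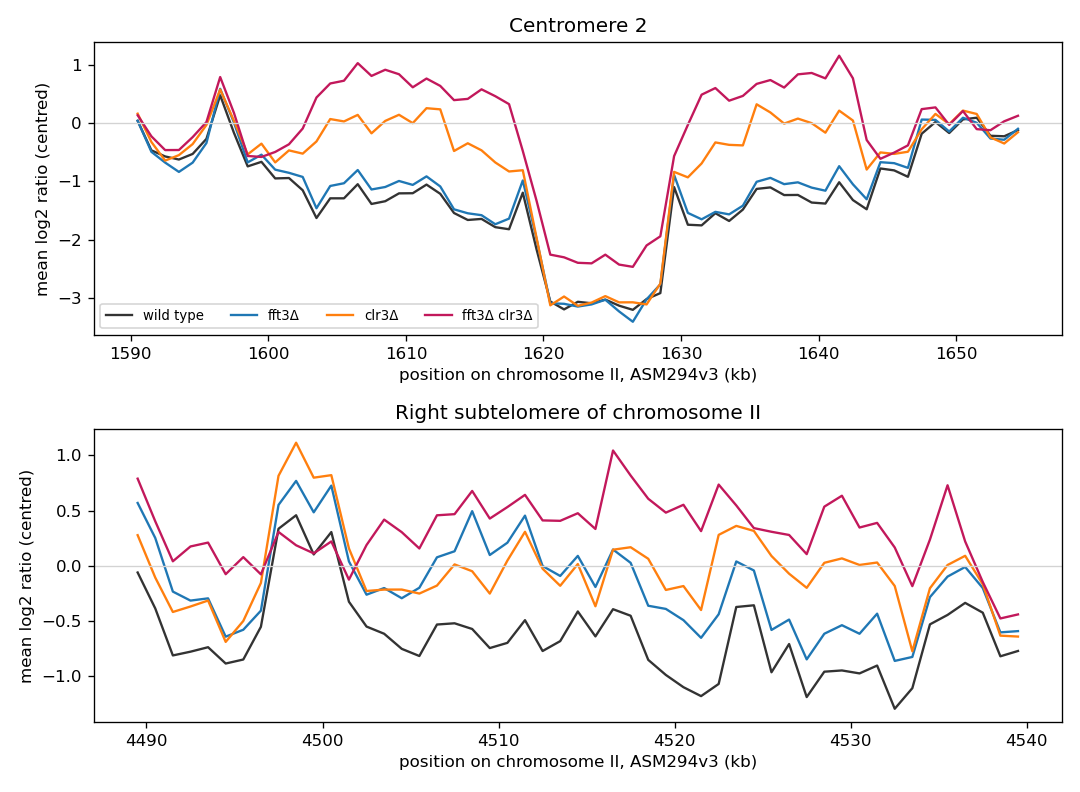
Centred log2 ratio of H3-FLAG ChIP to input (vertical axis) in 1-kb means along chromosome II, ASM294v3 (horizontal axis, kb), at centromere 2 and the right subtelomere, as a line per genotype (means of 3 wild-type and 2 fft3Δ arrays, single arrays otherwise). At the outer repeats clr3Δ and the double mutant run above wild type, by 1.21 and 2.00 on average, and along the subtelomere fft3Δ runs above wild type by 0.46.

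Of 2220 genes, limma called 69 higher and 24 lower in the double mutant than in wild type, against 129 and 162 at an unadjusted p under 0.05. The genes that rose were 34 of the 35 in the outer repeats, 28 of the 48 in the right subtelomere, 6 of the 13 within 20 kb of the left end of chromosome III, where the placing of the probes was weakest, and SPNCRNA.1095 further in (1.03, named after its value was seen). The largest was SPNCRNA.5262 (1616685–1617367) in the left outer repeats, at 2.30 ± 0.22 (SE, limma adjusted p = 0.000405; 2.08 on slide 3). SPNCRNA.5255, SPNCRNA.5260, SPNCRNA.5275, SPNCRNA.5265 and SPNCRNA.365 rose by 2.24, 2.23, 2.23, 2.21 and 2.21. In the subtelomere tlh2 rose by 1.41 ± 0.16 (limma adjusted p = 0.00104; 1.54 on slide 3), and gal1 and SPBCPT2R1.02, both among the highest in fft3Δ, rose by 0.80 and 1.28 (chosen after their values were seen). With probes found once in the genome 10 genes were called higher.

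All 24 genes that fell in the double mutant lay on the arm of chromosome II, 18 of them long noncoding RNA genes and 6 protein-coding. SPNCRNA.1572 (3008602–3011536) fell by 1.68 ± 0.15 (SE, limma adjusted p = 0.000262; −1.56 on slide 3), from 1.29 ± 0.14 in wild type, and SPNCRNA.1571, which overlaps it and shares probes with it, fell by 1.47. SPNCRNA.1550, SPNCRNA.1534, SPNCRNA.5867 and SPNCRNA.5917 fell by 1.29, 0.99, 0.92 and 0.90. The protein-coding genes were hsp16 (−0.82 ± 0.14, limma adjusted p = 0.0133), the glutathione peroxidase gene gpx1 (−0.61 ± 0.14, limma adjusted p = 0.0486), the stress-responsive nuclear envelope gene ish1 (−0.58), gem7 (−0.59), SPBC2A9.02 (−0.70) and SPBP4H10.12 (−0.59). The last 4 lie outside the rule for named genes and were chosen after their values were seen. In wild type 22 of the 24 had a log2 ratio above 0, with a median of 1.07 against 0.025 over all genes. With slide as a block 12 genes were called lower, with slide as a random block or with an intensity trend and robust variance 51, with probes found once 9, and without wild-type replicate 3 there were 13. The call of hsp16 ended without wild-type replicate 3 (−0.80, adjusted p = 0.0529), with equal spread (−0.77, adjusted p = 0.0581) and with quantile normalization (−0.65, adjusted p = 0.085). The call of gpx1 ended without wild-type replicate 1 (adjusted p = 0.0806) or 3 (0.124), without replicate 1 or 2 of fft3Δ (0.0812 each) and with slide as a block (−0.58, 0.129). It also ended with normexp (−0.68, adjusted p = 0.0629), arm centring (−0.56, 0.0708), quantile normalization (−0.51, 0.0678), the median over probes (−0.57, 0.0776) and probes found once (−0.61, 0.102).

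Of the gene lists, mating genes and tRNA genes rose in the double mutant. The 5 mating genes, of the mat1 and mat3 cassettes with mam1, rose by 0.48 on average (camera adjusted p = 0.0201; adjusted p = 0.578 with an estimated correlation), with 0.63 on slide 3 and adjusted p = 0.00311 with slide as a block; mat1-Mi and mat3-Mi differed by 0.74 and 0.70 and did not pass singly. But mat3-Mi passed with slide as a block (adjusted p = 0.0286), with slide as a random block both did (0.0449 each), and mat1-Mi did with quantile normalization (0.0292) and with an intensity trend and robust variance (0.0493). All probes of the 4 cassette genes are repeated, 3 each for mat1-Mi and mat3-Mi and 11 each for mat1-Mc and mat3-Mc. Members of the 2 cassettes are therefore not independent values. Input over the 5 genes differed by a mean of −0.28 from the wild-type array of slide 3, and by −0.22 in clr3Δ. Arrays of that slide also differed in input at a stretch of the mating-type contig (21551–22660), with −1.02 in the double mutant, −7.80 in clr3Δ and −7.82 in wild type. The 25 tRNA genes rose by 0.23 (camera adjusted p = 0.000361; adjusted p = 0.578 with an estimated correlation), but by 0.11 on slide 3, with adjusted p = 0.0618 with slide as a block, and by 0.044 with quantile normalization (adjusted p = 0.266); SPBTRNAVAL.06 and SPBTRNAARG.06 differed by 0.48 and 0.47. With probes found once 0 lists passed. Ribosomal protein genes (−0.15, adjusted p = 0.0858; −0.024 on slide 3, 0.939 with the block), core stress genes (−0.24, 0.222; −0.24, 0.439), long noncoding RNA genes (0.036, 0.222; 0.027, 0.447), rRNA genes (0.075, 0.497; 0.11, 0.439) and snoRNA and snRNA genes (−0.054, 0.944; −0.095, 0.519) did not pass as sets, and 3 lists passed without wild-type replicate 3. The rRNA value turned to −0.066 with normexp, −0.057 with quantile normalization and −0.22 with loess. Taken apart after seeing the data, the 7 rRNA genes of the ribosomal DNA differed by 0.29 (adjusted p = 0.0619; 0.33 on slide 3), which passed with slide as a block (0.0248) and without wild-type replicate 2 (0.35, adjusted p = 0.000421) and turned to −0.061 with quantile normalization and −0.052 with loess. The 7 5S genes of the arm differed by −0.14 (adjusted p = 0.306; −0.12 on slide 3, 0.464 with the block) and passed as lower with loess (−0.39). The median and the mean of the long noncoding RNA and the snoRNA and snRNA genes differed in sign (medians −0.032 and 0.0066). Over all genes 2 core stress genes (hsp16 and gpx1) and 1 chaperone gene (hsp16) fell, 57 long noncoding RNA genes rose and 18 fell, and tlh2 rose. Adjusted over the list alone the counts were 2 core stress genes and 1 chaperone gene lower, 58 long noncoding RNA genes higher and 22 lower, tlh2 higher, and 3 of 4 glycolysis, 2 of 3 histone and 2 of 14 snoRNA and snRNA genes lower, with 0 in the other lists. The double-mutant array stood apart in how its values followed the wild-type level. Over protein-coding arm genes its slope on the wild-type mean was 0.621, against 0.98 for clr3Δ. It also had the most nonuniform spots, 929.

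Among genes of those lists that did not pass over all genes in the double mutant, eno101 differed by −1.17 ± 0.27 (SE, limma adjusted p = 0.0557) and the glyceraldehyde-3-phosphate dehydrogenase gene tdh1 by −1.06 ± 0.30 (limma adjusted p = 0.118). The histone genes hht2 and hhf2 differed by −0.53 and −0.40, and snu1 and snoU14 by −0.52 and −0.71. The gene snu1 passed with normexp (−0.77, adjusted p = 0.0261), loess (−0.57, 0.0383), slide as a random block (−0.54, 0.0196) and an intensity trend with robust variance (−0.52, 0.0493), hht2 passed with loess (−0.65, 0.0474), and snoU14 with the trend (−0.71, 0.0493). Both glycolysis genes passed without wild-type replicate 2 (eno101 adjusted p = 0.00736, tdh1 adjusted p = 0.0149), and eno101 also without wild-type replicate 1 (0.0225) or 3 (0.0141), tdh1 without wild-type replicate 1 (0.0204). Both also passed with equal spread, with quantile normalization and with slide as a random block. Others were rpp202 (0.47) and rpl2701 (−0.40), SPRRNA.51 (0.49) and SPRRNA.47 (0.39), sks2 (−0.31), cdc18 (−0.27) and yox1 (0.25), gas2 (−0.38) and bgs1 (0.011), rec8 (−0.25) and rep1 (−0.13). SPRRNA.47 passed without wild-type replicate 2 in this comparison (adjusted p = 0.0296) and in clr3Δ (adjusted p = 0.0174). The genes str1, php4, tas3, clr1, fnx1 and scr1 differed by −0.16, −0.076, −0.15, −0.13, −0.13 and −0.11. Tf2-9 and Tf2-10 differed by 0.14 and 0.13, act1 by −0.30 ± 0.20 and mei4 by 0.055 ± 0.14.

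The effect of losing Fft3 in cells that already lacked Clr3 was asked with 1 array of each genotype, on the same slide. The double-mutant array exceeded the clr3Δ array at the outer repeats by 0.79 ± 0.21 (SE, with the spread taken from the replicated genotypes), at the central core by 0.75 ± 0.42 and at the subtelomere by 0.36 ± 0.11. All 3 passed at the preset correlation and none with an estimated one. The camera adjusted p-values were 1.7e-20, 5.71e-05 and 6.99e-10, with adjusted p = 0.112, 0.245 and 0.11 with an estimated correlation. The mating-type region (0.10 ± 0.30, camera adjusted p = 0.217) and Tf2 (0.24 ± 0.12, camera adjusted p = 0.0505) did not pass. Tf2 passed without wild-type replicate 2 (0.24, adjusted p = 0.0466), and the mating-type region at probes found once (0.12). The call at the core turned with normexp (−0.41) and with quantile normalization (−0.033). Whether compression of values on the double-mutant array raised the core was not tested. limma called 2 of 2220 genes, SPNCRNA.1572 at −1.65 and SPNCRNA.1571 at −1.47, both lower in the double mutant (adjusted p = 0.0165 each), against 74 higher and 99 lower at an unadjusted p under 0.05. These were 0 without wild-type replicate 3 or without either replicate of fft3Δ, 36 with quantile normalization, 28 with slide as a random block, 8 with an intensity trend and robust variance and 4 with normexp. The 25 ribosomal protein genes fell, with a mean of −0.18 (camera adjusted p = 0.0182; adjusted p = 0.69 with an estimated correlation; 0.0123 with slide as a block), and 0 of them passed singly. Other lists tested did not pass: core stress genes (−0.28, adjusted p = 0.11), tRNA genes (0.078, 0.256), mating genes (0.18, 0.331), rRNA genes (−0.10, 0.473; −0.42 with loess, which passed; taken apart −0.039 for the 5S genes of the arm and −0.16 for those of the ribosomal DNA, −0.34 and −0.50 with loess, of which the second passed, and the first turned to 0.022 with quantile normalization), snoRNA and snRNA genes (−0.084, 0.473) and long noncoding RNA genes (−0.0029, 0.636; camera's direction was up where their mean and median were below 0). Over all genes the 2 noncoding RNA genes passed; adjusted over the list alone they did as well, with 2 core stress, 1 chaperone and 2 histone genes lower and 0 in the other lists.

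Whether the effects of the 2 deletions add up was asked with the interaction, the effect of losing Fft3 without Clr3 minus its effect with Clr3. New H3 exceeded the sum of the single-mutant differences by 0.62 ± 0.25 (SE) at the outer repeats, 0.75 ± 0.50 at the central core and 0.41 ± 0.14 at the Tf2 elements. With slide as a block these were 0.57, 0.62 and 0.46. Compression of values on the double-mutant array could enter the core value, which was not tested. They passed camera at the preset correlation (adjusted p = 1.22e-11, 0.00073 and 0.00323) and not with an estimated correlation (adjusted p = 0.313 for each). The core value did not pass with equal spread (0.29) and turned to −0.016 with quantile normalization and −0.056 with normexp, and the Tf2 value turned to −0.16 with loess. At the subtelomere the interaction was −0.10 ± 0.14 (camera adjusted p = 0.317), which passed with loess (−0.24). At the mating-type region it was −0.18 ± 0.36 (camera adjusted p = 0.192), which passed as lower without wild-type replicate 1 (−0.27) and without replicate 2 of fft3Δ (−0.39). limma called 0 genes, against 42 higher and 97 lower at an unadjusted p under 0.05; 2 were called without wild-type replicate 2, 14 with quantile normalization, 4 with an intensity trend and robust variance and 2 each with normexp, loess or slide as a random block. The 25 ribosomal protein genes were lower than the sum by a mean of −0.25 (camera adjusted p = 0.00442; adjusted p = 0.954 with an estimated correlation), which did not pass with slide as a block (adjusted p = 0.0557). Other lists tested did not pass: core stress (−0.30, adjusted p = 0.181), snoRNA and snRNA (−0.16, 0.252), rRNA (−0.07, 0.872; −0.50 with loess, which passed; taken apart −0.063 for the 5S genes of the arm and −0.077 for those of the ribosomal DNA, −0.56 and −0.44 with loess, which both passed, and the first turned to 0.045 with equal spread and 0.055 with quantile normalization), long noncoding RNA (−0.028, 0.872), mating (0.062, 0.872) and tRNA genes (−0.037, 0.872). Adjusted over the list alone 2 core stress genes, 1 chaperone gene and 1 histone gene were lower, against 0 over all genes, and 0 in the other lists.

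All 31 genes higher in clr3Δ were also higher in the double mutant, where independent lists of those sizes would share 0.964. That number takes genes as independent, but most of the 31 lie together in the outer repeats. Unchanged groups simulated against the same wild-type arrays shared 0 on average over 100 simulations. Almost no gene is called in unchanged groups, so this 0 was fixed in advance and is no reference for the 31. Without wild-type replicate 2 the overlap was 51, and with probes found once 2. Across the 2220 genes, which are not independent replicates, the differences of fft3Δ and clr3Δ from wild type correlated at 0.549 (0.317 simulated), with a covariance of 0.0186 (0.00725 simulated). For fft3Δ and the double mutant these were 0.361 (0.314) and 0.0196 (0.0072), and for clr3Δ and the double mutant 0.721 (0.252) and 0.068 (0.00731). With wild-type replicates 1 and 2 as controls for fft3Δ and replicate 3 for the other genotype, a choice made after seeing the data so that no control was shared, fft3Δ correlated with clr3Δ at 0.326 (covariance 0.0128) and with the double mutant at 0.268 (0.016). With replicate 3 for clr3Δ and replicates 1 and 2 for the double mutant the correlation was 0.545 (0.0557), and the other way round 0.632 (0.0622). The simulations held no slide effect, so part of the excess of clr3Δ and the double mutant may also come from slide 3, which they share.

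Input DNA was compared as a measure of copy number in 432 windows of 5 kb. limma called 0 windows in any comparison, against 3 at an unadjusted p under 0.05 for fft3Δ, 0 for clr3Δ, 26 for the double mutant, 12 for the double mutant against clr3Δ and 2 for the interaction. With slide as a block it called 0, 5, 8, 7 and 2. Over the right subtelomere the input of fft3Δ differed from wild type by 0.011 on slide 1 and 0.0076 on slide 2. Over the outer repeats it differed by 0.59 and 0.11 on those slides, and that of clr3Δ and the double mutant by −0.15 and −0.51 from the wild-type array of slide 3. In the same order the input differences were −0.20, −0.089, −0.33 and −0.11 over the mating-type region. Over Tf2 they were 0.024, 0.46, −0.026 and −0.50. At the left end of chromosome III, where the placing of the probes was weakest, input differed by 0.26 and 0.63 for fft3Δ within slides 1 and 2, by 1.21 for clr3Δ and by 2.47 for the double mutant.

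**Figure D3:**
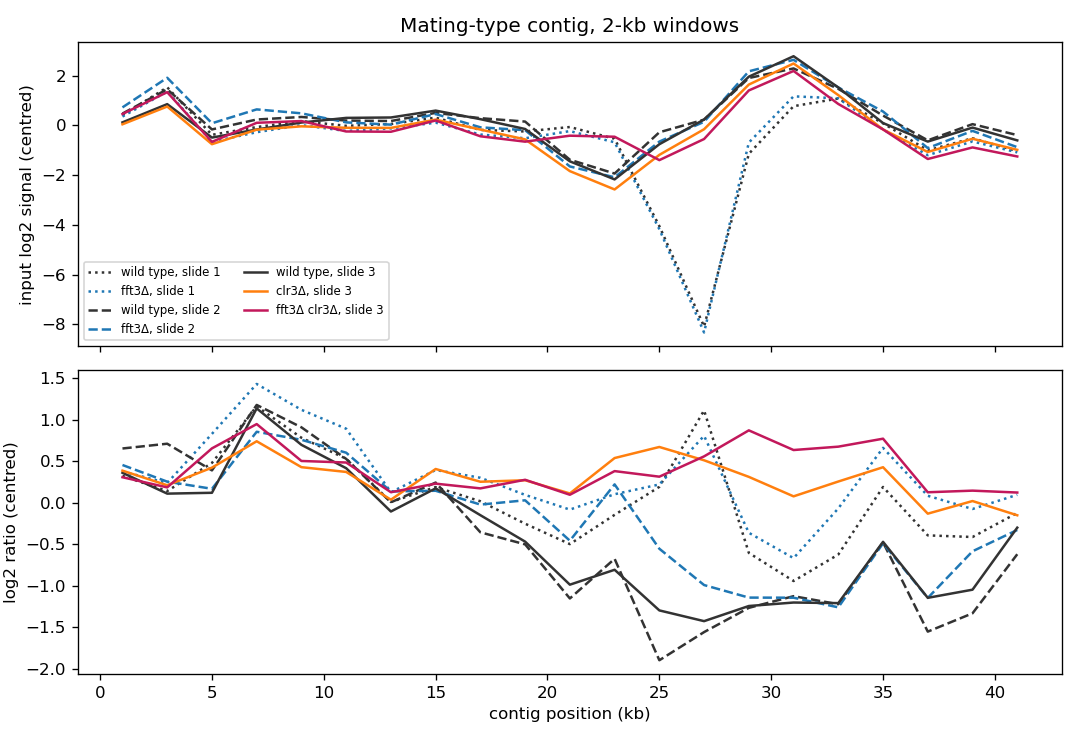
Centred log2 input signal and centred log2 ratio of ChIP to input (vertical axes) in 2-kb windows along the mating-type contig (horizontal axis, kb), as a line per array coloured by genotype with the line style giving the slide. Around 27 kb the input of both slide 1 arrays drops to −8.09 and −8.33, and between 28 and 34 kb clr3Δ and the double mutant lie 1.43 and 1.94 above the wild-type array of their slide, as they do by 1.97 and 1.61 from 24 to 26 kb and by 1.94 and 1.98 from 26 to 28 kb. On slide 2 fft3Δ lies 1.34 above wild type from 24 to 26 kb and 0.57 from 26 to 28 kb.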

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

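No test in this part was chosen after the result was seen, but an allowance for spread was added to the reading of the tests once their values were known. On these arrays the double mutant exceeded the sum of both single mutants at the outer centromere repeats by 0.62 ± 0.25 (SE), past its test at the preset correlation and not with an estimated one. The narrower spread of log ratios on the double-mutant array stays open. It was 0.348, against 0.344, 0.449 and 0.381 on wild-type replicates 1, 2 and 3, so a wild-type array was as narrow. With every array scaled to equal spread the excess was 0.56, above the bound of 0.31 but within its spread of 0.33. Repeated probe sequences stay open likewise, with 0.51 ± 0.36 at probes found once in the genome. A lower input signal stays open too, since the input difference of the same contrast was −0.57 ± 0.50, below the bound of −0.31 but within its spread. Lower input could raise the ratio only where the ChIP signal did not fall with it, as it would with copy number. That both factors act together there is a hypothesis, not tested, that rests on a single double-mutant array.

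At the central core (0.75 ± 0.50) and the Tf2 elements (0.41 ± 0.14) the same contrast also passed at the preset correlation and not with an estimated one. Input at Tf2 differed by −0.47 between the double mutant and clr3Δ, and by 0.16 between fft3Δ and wild type. Whether this raised the Tf2 value was not tested. Nor was it tested whether compression of values on the double-mutant array raised the core value. The core value was 0.29 and did not pass with equal spread, and was −0.056 with normexp and −0.016 with quantile normalization; the Tf2 value was −0.16 with loess.

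Signal in the mating-type contig, which no comparison used, stood out in 3 places. Input DNA over 61 probes (25551–28610 of the contig) averaged −8.27 on both arrays of slide 1 and −0.14 on the other 5, and 95.1% of those spots were dim on slide 1 against 0 on the others. That stretch was bounded by runs of dim probes on wild-type replicate 1, and the next by those on wild-type replicate 3. Low values on these arrays themselves follow from that choice. Over 22 further probes (21551–22660) input was −7.82 on wild-type replicate 3, −7.80 on clr3Δ, −7.54 on wild-type replicate 2 and −7.63 on fft3Δ replicate 2, against −1.29, −1.39 and −1.02 on wild-type replicate 1, fft3Δ replicate 1 and the double mutant. Wild-type arrays thus differed from each other in input there, while wild type and fft3Δ of the same slide were close. Differences from the wild-type mean at the mating-type region may therefore compare unlike loci. The labels name no difference between the strains at the mating-type locus, and none was tested. Between 28 and 34 kb of the contig (120 probes), where wild type averaged −1.05 ± 0.28 (SD, n = 3), clr3Δ stood 1.43 and the double mutant 1.94 above the wild-type array of their slide, without a test, and their input differed from it by −0.31 and −0.60. From 24 to 26 kb they stood 1.97 and 1.61 above that array, and from 26 to 28 kb 1.94 and 1.98. On slide 2 fft3Δ stood above wild type by 1.34 from 24 to 26 kb and 0.57 from 26 to 28 kb, but by 0.022 between 28 and 34 kb.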

How the results depend on the processing

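Leaving out both arrays of slide 1, and the interval from rpp202 to emc3, were chosen after seeing the data. Values kept their direction and side of the threshold with the deposited log2 values, probes well above background alone, at least 4 probes per gene, wild type and fft3Δ alone, 5-kb windows and the interval. Where a value changed, the cause was not tested, apart from fewer genes or arrays entering. Across settings the outer repeats ranged from 0.91 to 1.34 in clr3Δ and from 1.71 to 2.17 in the double mutant, and the subtelomere from 0.38 to 0.56 in fft3Δ, 0.42 to 0.70 in clr3Δ and 0.81 to 1.05 in the double mutant. Normexp gave 4 genes for the double mutant against clr3Δ and 2 for the interaction, and the core −0.35 in fft3Δ, −0.15 in the double mutant, −0.41 for the double mutant against clr3Δ and −0.056 for the interaction. Equal spread gave 2 lists in clr3Δ, the core 0.35 in fft3Δ and 0.29 for the interaction, and Tf2 0.22 in the double mutant and 0.30 against clr3Δ. Tf2 in the double mutant against clr3Δ passed at 0.26 with arm centring, 0.25 with the median over probes, 0.24 with 1-kb windows and 0.24 with the intensity trend. Quantile normalization gave 36 genes for the double mutant against clr3Δ, 14 for the interaction, and 3, 0 and 1 lists in fft3Δ, clr3Δ and the double mutant. It moved the outer repeats in fft3Δ to −0.017, the core to 0.026 in the double mutant, −0.033 against clr3Δ and −0.016 for the interaction, and Tf2 to 0.29 in the double mutant and 0.36 against clr3Δ. Loess gave 2 genes for the interaction, 0 lists in fft3Δ and 3 in clr3Δ, Tf2 0.045 in fft3Δ and −0.16 for the interaction, and the subtelomere −0.24 for the interaction. Without repeated probes 2 genes were higher in clr3Δ, 10 higher and 9 lower in the double mutant, 2 shared, with 3, 0 and 0 lists; the mating-type region was 0.0802 in clr3Δ and 0.12 in the double mutant against clr3Δ, and the Tf2 interaction 0.28. With slide as a replicate block 12 genes were lower in the double mutant, 2 lists passed in clr3Δ and 1 in the double mutant, no other count of genes, lists or shared genes moved by over 1.5 times and no region call changed, while input windows called went from 0 to 5, 8, 7 and 2 in clr3Δ, the double mutant, the double mutant against clr3Δ and the interaction; 2 pairs of arrays are too few to show that numbers pair the samples. With slide as a random block 3 genes were higher in fft3Δ, 50 in clr3Δ, 51 lower in the double mutant, 28 differed between the double mutant and clr3Δ, 2 for the interaction, 49 were shared, and the core was 0.056 in fft3Δ and −0.059 in clr3Δ. The intensity trend gave 5 higher in fft3Δ, 51 lower in the double mutant, 8 against clr3Δ and 4 for the interaction. A threshold of 0.01 left 6 lower in the double mutant, 0 against clr3Δ and 1 list in the double mutant. With an estimated correlation 0, 0 and 0 lists passed, and calls ended at the outer repeats (0.17), mating-type region (0.28) and Tf2 (−0.17) in fft3Δ, the mating-type region in clr3Δ (0.29), the core (0.81) and mating-type region (0.39) in the double mutant, the outer repeats (0.79), core (0.75) and subtelomere (0.36) of the double mutant against clr3Δ, and for the interaction at the outer repeats (0.62), core (0.75) and Tf2 (0.41). Slide 1 alone gave 0.35 at the outer repeats and 0.062 at the core in fft3Δ; slide 2 gave 0.19 at the core, 0.55 at the subtelomere and −0.28 at Tf2; slide 3 gave −0.20 at the core and −2.44e-05 at Tf2 in clr3Δ and 0.24 at Tf2 in the double mutant. Without both arrays of slide 1, 13 genes were lower in the double mutant, 3 lists passed in clr3Δ and the outer repeats in fft3Δ were at 0.00103. Leaving out 1 replicate at a time gave 0 to 7 genes higher in fft3Δ (7 without wild type 1), 32 to 54 higher in clr3Δ (54 without wild type 2) and 0 to 1 lower (1 without wild type 2). It gave 13 to 35 lower in the double mutant (13 without wild type 3, 16 without wild type 1), 0 to 3 differing from clr3Δ (0 without wild type 3 or either fft3Δ), 0 to 2 for the interaction (2 without wild type 2) and 32 to 51 shared (51 without wild type 2). Lists numbered 0 to 3 in fft3Δ (0 without fft3Δ 1, 3 without fft3Δ 2), 1 to 3 in clr3Δ (3 without wild type 1 or 2) and 2 to 3 in the double mutant (3 without wild type 3). In fft3Δ the outer repeats ranged from 0.014 to 0.33 and the mating-type region from 0.075 to 0.49 (both calls ended without fft3Δ 1), and the core from −0.18 to 0.16 (called without wild type 2). Tf2 ranged from 0.083 to 0.18 in the double mutant and was 0.24 against clr3Δ throughout (both called without wild type 2), and the mating-type interaction from −0.39 to 0.028 (called without wild type 1 and without fft3Δ 2). Of the 148 values of named genes, 9 came past the threshold with the intensity trend and 8 with the random block, and 5 fell short of it at 0.01; gpx1 in the double mutant fell short most often (0.129 with the block). Few probes were dim. The normexp setting, which turned values at the core, also used median signals and an offset, so which of these moved them is open.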

Other observations

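The test of slide for the subtelomere, the tests of differences of the lower arm genes, the tRNA and chromosome III values and the interval from rpp202 to emc3 were chosen after results were seen; the other tests were not. Of the 25 tRNA genes, 18 lie within 10 kb of centromere 2, where tRNA clusters border heterochromatin. Their median log2 ratio in wild type was −0.78, and the median differences were 0.12 in fft3Δ, 0.20 in clr3Δ and 0.32 in the double mutant, with 17 of 18 higher in each. For the other 7 the wild-type median was −0.36 and the differences 0.083, 0.045 and 0.10, with 7, 6 and 5 of 7 higher. Against the wild-type array of slide 3 the mean over all 25 was 0.032 in clr3Δ and 0.11 in the double mutant. Under quantile normalization the mean of all 25 turned to −0.067 in clr3Δ.

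The left end of chromosome III (III: 1–20020, ASM294v3), which holds ribosomal DNA, stood at −0.58 ± 0.06 (SD, n = 3) in wild type. It was higher by 0.63 ± 0.11 (SE) in clr3Δ (camera adjusted p = 7.07e-13; adjusted p = 0.0286 with an estimated correlation; 0.65 on slide 3) and by 0.73 ± 0.11 in the double mutant (camera adjusted p = 2.72e-08; adjusted p = 0.0563 with an estimated correlation; 0.75 on slide 3). In fft3Δ it differed by 0.09 ± 0.09 (exact permutation p = 0.5), with 0.24 and −0.082 on slides 1 and 2. All 399 probes are repeated, and their input ranged from −0.023 in wild type replicate 3 to 2.44 in the double mutant. Within the mating-type region, the interval from rpp202 to emc3 (2128461–2138320) differed by 0.46 ± 0.33 in fft3Δ (exact permutation p = 0.3), and by 0.78 and 0.99 on slide 3 in clr3Δ and the double mutant.

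The higher ratio of fft3Δ over the right subtelomere (0.46) was weighed against 3 technical explanations. Exactly repeated probe sequences as its whole cause are argued against by the difference of 0.38 ± 0.13 at probes found once, above the bound of 0.23. Probes found once may still bind near copies, which were not counted, so signal from those stays open. A lower input signal as its cause would need an input difference of −0.20 or lower, and the larger of the within-slide differences was 0.011. A slide effect is argued against by the smaller of the within-slide differences, 0.394 ± 0.11 (SE), above the SD of 0.10 between wild-type arrays. Less suppression of nucleosome turnover without Fft3 may account for the difference; this is a hypothesis about turnover, which was not measured itself, found and tested on the same 5 arrays, which allow no permutation p under 0.1.

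The 24 arm genes lower in the double mutant had a median wild-type level of 1.07, against 0.025 over all genes, a gap that partly follows from choosing genes by their difference from wild type. Scaling every array to equal spread cannot decide whether a narrower spread of log ratios on the double-mutant array caused their fall. Before scaling its spread was 0.348, against 0.344, 0.449 and 0.381 on wild-type replicates 1, 2 and 3, so a wild-type array was as narrow. After scaling 22 genes were called lower. Of the 24, 14 were among them, within the spread of 2.4 of a bound of 12. The median difference of the 24 went from −0.74 (median SE 0.14) to −0.75 (median SE 0.15), beyond a bound of −0.37. Each of the 10 whose call ended had a larger SE, and its difference was 0.885 to 1.01 times that before scaling. A compression of values on the whole array stays open: over the other 2035 arm genes they had a slope of 0.651 on the wild-type mean, and dividing by it left a median of −0.62 (median SE 0.20), part of which could be chance, since these genes were chosen for their fall on that array. A change of transcription or turnover at these genes was not tested, and a single double-mutant array cannot separate it from that array's own quality.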
